A study of Mus musculus with 16 samples.

How the data were processed

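RNA from the mucosal layer of the proximal colon was profiled on Affymetrix arrays, 1 array per sample, in 16 samples. Per the labels' protocols, male C57BL/6J mice ate a control diet or feed with 320 ppm sulindac, a non-steroidal anti-inflammatory drug, for 10 weeks from 6 weeks of age. Inflamed areas were collected from sulindac-fed mice and matching normal tissue from control-fed mice. Knockout (KO) mice lost a floxed Mcc gene in intestinal epithelium through a villin promoter driving Cre, and their siblings with floxed Mcc and no Cre are called wild type (WT) here. The groups held 6 WT control, 3 WT sulindac, 3 KO control and 4 KO sulindac arrays, taken from the genotype and diet labels.

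The deposited values are log2 expression from RMA, which corrects background, normalises quantiles across arrays and summarises probes per transcript cluster. RMA and Affymetrix Power Tools 1.16.1 are named in the submitters' processing notes. The genome build and annotation version are not given in the sources used here, so no coordinates are printed. RMA compresses differences near background and gives no detection call, so fold changes of dim genes are uncertain. Where the lower group of a gene lies under the array medians, its fold is read as a lower bound and not ranked against others. The number of arrays limits the precision, and array medians of all rows lay between 4.90 and 5.05 on the log2 scale.

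The value table held 72688 rows, of which the probe-to-gene table listed 32750. Of these, 31261 had 1 gene symbol and 1489 had several, and 39938 rows were not listed. Symbols were updated through the mouse RefSeq gene table of GRCm38.p6 where they had changed, which gave 1140 genes another symbol. For the 441 genes with more than 1 row, the row with the highest mean over all arrays was used, which left 30705 genes. Rows with several symbols or none entered no comparison of named genes. No column of per-sample values was left out. No pair of arrays within a group was a duplicate, as their correlations lay between 0.983 and 0.996 and at most 0.0358% of their values were identical. The descriptions give each array a number of its own, but no label states which arrays come from separate animals. The p-values therefore measure the spread between these samples, pooled over all groups in a fit.

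Genes were tested with limma 3.58.1 in R 4.3.3, in 1 fit of 4 group means over all 16 arrays with empirical Bayes moderation, two-sided. A gene was called where the Benjamini-Hochberg adjusted p over all 30705 genes was under 0.05. The 5 comparisons were the sulindac response in each genotype, the genotype difference on each diet and the interaction of genotype with diet. The 39 gene lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The camera p-values were adjusted over the lists. The estimated correlations lay between 0.044 and 0.831, all above the preset value, so list calls that hold only at the preset value are weak. The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes Mcc, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap, and 2 members of at most 8 moved lists per comparison. It also takes the genes with the lowest p where few or no genes passed, and leaves model names such as Gm and Rik symbols out of the largest changes.

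On simulated data with 200 changed genes among the 30705, log2 changes of 1 were recovered in 89.6% of cases in the WT response, 88.1% in the KO response, 92.5% in the genotype difference on the control diet, 86.6% in that on sulindac and 85.1% in the interaction. Changes of 0.5 were recovered in 53.7%, 52.2%, 67.2%, 50.7% and 26.9%, in the same order. Between 3 and 12 unchanged genes were called per simulation. The noise was drawn independently for each gene, with the same SD in every group. In the data, the 8 largest rises between lesions had SDs of 0.31 to 1.25 in KO lesions. Their SDs in KO controls were 0.06 to 0.19, and genes within lists were correlated. The recovery rates and false calls therefore hold for the simulated noise only. They were not tested for correlated genes or for lesions that vary more than controls.

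Numbers in the sample descriptions fall into a lower and a higher series, which may mark cohorts. WT controls hold both series, KO controls only the higher series, and every sulindac array the lower. The KO response is therefore fully confounded with the series, and only the WT controls link the series where it enters as a covariate or random block. The replicate numbers were checked for pairing. Samples of the same number deviated together in the WT response (r from 0.13 to 0.36 over 3 pairs) and in the genotype difference on sulindac (r from 0.35 to 0.63). They did not in the KO response (r from -0.35 to -0.17) or in the genotype difference on the control diet (r from -0.41 to -0.31). The replicate numbers come from the sample titles and no label says what they share, so the pairing in the first 2 of these rests on the data alone.

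Alternatives were the groups compared fitted alone, the replicate number as a block, the number series as a covariate or random block, the arrays of 1 series alone, all named transcript clusters, the dimmest 40% of genes left out, repeated quantile normalisation, centring of arrays on their medians, a variance trend with robust moderation, array weights, the smooth muscle list mean as a covariate and each array left out in turn. Chosen after seeing the data were an inflammation covariate over the 7 sulindac arrays, a fit without WT controls 1 and 2, which stood apart on the second principal component, and a fit of all rows. Xist lay between 3.93 and 4.15 on every array and the Y-linked genes Kdm5d, Eif2s3y and Uty were at least 6.73, as in male animals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.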

Results

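Colon mucosa from inflamed areas of sulindac-fed mice, called lesions here, was compared with matching normal mucosa of control-fed mice, in Mcc wild-type (WT) animals and in animals with an epithelial Mcc knockout (KO). Mcc is named for its mutation in colorectal cancers. The comparisons ask what differed between lesions and control mucosa in each genotype, called the sulindac response, and where the genotypes differed. No array holds uninflamed tissue of sulindac-fed mice, so effects of the drug and of choosing inflamed tissue cannot be told apart. There were 6 WT control, 3 WT sulindac, 3 KO control and 4 KO sulindac arrays, and 30705 genes were tested. Diet, and with it the choice of inflamed tissue, separated the arrays along the first principal component, which held 54.5% of the variance.

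Mcc was lower in every KO array than in every WT array. By replicate it was 7.08, 7.06, 7.17, 7.35, 7.22 and 7.09 in WT controls, 7.40, 7.09 and 7.18 in WT lesions, 6.57, 6.71 and 6.43 in KO controls, and 6.39, 6.42, 6.48 and 6.45 in KO lesions. Its log2 level was 7.16 ± 0.11 (SD, n = 6) in WT controls, 7.22 ± 0.16 (SD, n = 3) in WT lesions, 6.57 ± 0.14 (SD, n = 3) in KO controls and 6.44 ± 0.03 (SD, n = 4) in KO lesions. The difference was -0.60 (SE 0.08) on the control diet, with a limma adjusted p of 0.083 that missed the threshold, and -0.79 (SE 0.09) on sulindac, with an adjusted p of 0.0032. With the replicate block the value on sulindac was -0.82 with an adjusted p of 0.0757, which ended the call. The probes may lie partly outside the deleted part, and cells other than epithelium keep the gene. KO lesion 3 had Mcc at 6.48, below all WT arrays.

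**Figure D1:**
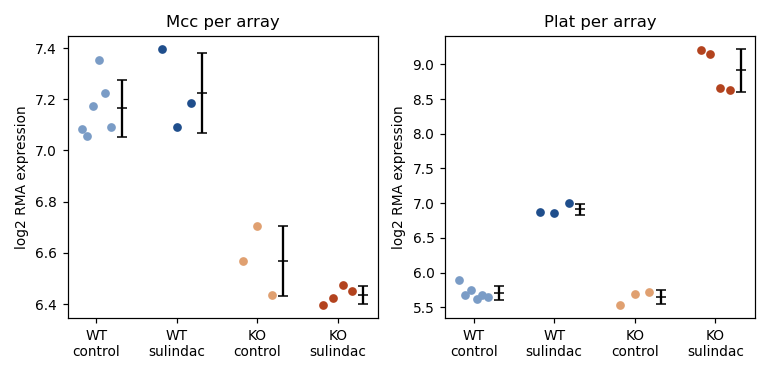
Log2 RMA expression of Mcc and Plat on each of the 16 arrays, by group, with the group mean and SD as bars to the right of the points. Mcc is below every WT array in all KO arrays, and Plat lies between 8.62 and 9.21 in KO lesions against at most 6.999 in WT lesions.

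In the response of WT mice to sulindac, the rises named by size among called genes whose arrays did not overlap were those of inflammatory and matrix-degrading genes. Lists of differentiated epithelial genes were lower, though their camera calls held at the preset correlation alone. Mmp13, a collagenase, rose 93.6-fold (log2 6.55, SE 0.18), and Mmp10, a stromelysin, rose 46.6-fold. The cytokine genes Il1b and Il1a rose 64.8-fold and 62.4-fold, and Cxcl9, a chemokine that attracts T cells, rose 54.6-fold. The calprotectin genes S100a8 and S100a9 rose 59.4-fold and 29.1-fold, and Ptgs2, the inducible cyclooxygenase that sulindac inhibits, rose 38.4-fold. In WT controls S100a8, Il1a, Iigp1, Mmp10, S100a9 and Mmp13 had log2 means of 3.14, 4.06, 4.44, 4.69, 4.76 and 4.88, under the array medians of 4.90 to 5.05, so their folds are lower bounds. Among the falls, Mptx1 and Mptx2, mucosal pentraxins, had log2 changes of -6.50 (SE 0.86) and -5.50 (SE 0.74), and Tgm3, a transglutaminase, had -4.01. WT control 3 stood low for both pentraxins, with Mptx1 at 7.91 against 11.6 to 13.1 in the other WT controls. Sult1a1, a sulfotransferase, Cyp2c68, a cytochrome P450, and Ugt2b5, a glucuronosyltransferase, changed by -3.85, -3.64 and -3.01. Trpm6, a magnesium channel, fell by 3.25 and Scin, an actin-severing protein, fell by 2.92 on the log2 scale. Mptx2, Ugt2b5 and Cyp2c68 lay at 4.29, 4.42 and 4.63 in WT lesions, so their changes are lower bounds in size.

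Of 30705 genes, 4714 passed in this response, 2144 higher and 2570 lower, and 536 of the rises and 263 of the falls were at least 2-fold. Of 39 gene lists, 25 moved, 18 up and 7 down, and 11 of them held with an estimated correlation. Interferon-stimulated genes had 22 of 25 members higher and none lower, 22 also adjusted over the list alone, with Gbp2 at 18.6-fold and Iigp1 at 21.3-fold, a lower bound (adjusted p = 0.0179 with an estimated correlation). Matrix proteases and inhibitors had 18 of 21 higher, and 18 adjusted over the list alone (adjusted p = 9.23e-04 with an estimated correlation). Monocyte and macrophage genes had 17 of 21 higher, 19 higher and 1 lower adjusted over the list alone, with Ly6c2 at 17.4-fold and Lyz2, lysozyme, at 8.39-fold (adjusted p = 0.0054 with an estimated correlation). Fibroblast and collagen genes had 18 of 23 higher, 18 higher and 2 lower adjusted over the list alone, with Dcn, decorin, at 13.6-fold and Fn1, fibronectin, at 6.76-fold (adjusted p = 0.0185 with an estimated correlation).

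Genes of regenerating and fetal-like epithelium had 18 of 25 higher, 19 adjusted over the list alone, with Ly6c1 at 11.9-fold and F3, tissue factor, at 11.2-fold (adjusted p = 0.0185 with an estimated correlation). Ly6c1 went from 6.92 in WT controls to 10.49 in WT lesions, close to Ly6c2 of the macrophage list (6.94 to 11.06). Which cells carried the changes of this list was not tested in either genotype, so it does not show that epithelium regenerated. Complement and coagulation genes had 16 of 25 higher, 18 higher and 1 lower adjusted over the list alone, with C1s1 at 7.52-fold (adjusted p = 0.0016 with an estimated correlation). Cytokines and chemokines had 17 of 32 higher, 22 higher and 1 lower adjusted over the list alone (adjusted p = 0.0332 with an estimated correlation). Hypoxia and glycolysis genes had 15 of 25 higher, 17 adjusted over the list alone, with Adm, adrenomedullin, at 4.73-fold and Egln3, a prolyl hydroxylase, at 3.82-fold (adjusted p = 0.0185 with an estimated correlation). MHC class II genes had 9 of 13 higher, 9 adjusted over the list alone, and T and NK cell genes 11 of 20, 16 adjusted over the list alone (adjusted p = 0.0218 and 0.0295 with an estimated correlation). Epithelial antimicrobial genes had 13 of 23 higher and 2 lower, 13 and 3 adjusted over the list alone (adjusted p = 0.0056 with an estimated correlation). Neutrophil genes had 13 of 20 higher, 14 adjusted over the list alone, but missed the threshold with an estimated correlation (adjusted p = 0.0637 with an estimated correlation).

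Epithelial function genes were lower in WT lesions, though none of these list calls held with an estimated correlation. For colonocyte, goblet and enteroendocrine genes the list means of single arrays did not overlap. They were at least 9.93, 10.07 and 6.60 in WT controls against at most 9.43, 9.63 and 6.07 in WT lesions. Xenobiotic metabolism genes had 19 of 39 lower and 2 higher, 24 and 3 adjusted over the list alone (adjusted p = 0.1639 with an estimated correlation). Absorptive colonocyte genes had 14 of 27 lower and 2 higher, 17 and 3 adjusted over the list alone (adjusted p = 0.1758 with an estimated correlation). Goblet cell genes had 15 of 25 lower and 1 higher, 19 and 3 adjusted over the list alone (adjusted p = 0.1639 with an estimated correlation). Enteroendocrine genes had 11 of 21 lower and none higher, 13 adjusted over the list alone (adjusted p = 0.0681 with an estimated correlation). PPAR targets and fatty acid oxidation genes had 17 of 30 lower and 1 higher, 20 and 1 adjusted over the list alone, and tuft cell genes 8 of 20 lower, 11 lower and 1 higher adjusted over the list alone (adjusted p = 0.1639 for both with an estimated correlation).

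Other lists also moved in WT lesions, and none of these calls held with an estimated correlation. Junction and keratin genes had 9 of 26 higher, 13 adjusted over the list alone, and immediate early genes 6 of 22, 9 adjusted over the list alone (adjusted p = 0.1049 and 0.2467 with an estimated correlation). Endothelial genes had 5 of 20 higher, 7 adjusted over the list alone, smooth muscle genes 3 of 20 and B and plasma cell genes 2 of 19, the same adjusted over the list alone (adjusted p = 0.2451, 0.4750 and 0.4750 with an estimated correlation). The B and plasma cell list lost its call without WT lesion 1 or 2 (adjusted p = 0.1164 and 0.0657). Adipocyte genes had 3 of 14 lower, 3 adjusted over the list alone (adjusted p = 0.2474 with an estimated correlation). Cell proliferation genes had 2 of 29 higher and a median of 0.55 (0.36 without WT lesion 3), with none passing adjusted over the list alone (adjusted p = 0.4095 with an estimated correlation). The eicosanoid list, which holds Ptgs2, had 7 of 35 members higher and 8 lower and did not move as a set by camera (adjusted p = 0.2255).

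KO mice on sulindac showed a response of the same kind. S100a8 rose 176.9-fold (log2 7.47, SE 0.38), Mmp13 165.5-fold, Il1b 134.9-fold, Il1a 122.4-fold and S100a9 106.7-fold. Mmp10 rose 87.6-fold, Ptgs2 74.2-fold and Retnlg, a resistin-like gene of neutrophils, 60.4-fold. In KO controls S100a8, Retnlg, Il1a, S100a9, Mmp10, Iigp1 and Mmp13 had log2 means of 3.12, 3.21, 4.03, 4.65, 4.68, 4.69 and 4.86. These lay under the array medians, so the folds of these genes are lower bounds. The falls of Mptx2 and Cyp2c68, at 4.57 and 4.76 in KO lesions, are lower bounds in size too. Mptx1, Mptx2 and Tgm3 fell by 7.53, 6.66 and 4.39 on the log2 scale, and Sult1a1 and Cyp2c68 by 3.68 and 3.65. Hao2, a hydroxyacid oxidase, Otc, a urea cycle enzyme, and Insl5, a hormone of enteroendocrine cells, fell by 3.37, 3.29 and 3.22.

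In this response 6472 genes passed, 2760 higher and 3712 lower, of which 722 and 438 were at least 2-fold. Of the lists 25 moved, 17 up and 8 down, and 10 of them held with an estimated correlation. Neutrophil genes had 17 of 20 higher, 17 adjusted over the list alone (adjusted p = 0.0398 with an estimated correlation). Cytokines and chemokines had 27 of 32 higher and 2 lower, 28 and 2 adjusted over the list alone (adjusted p = 0.0398 with an estimated correlation). Matrix proteases had 19 of 21 higher, 19 adjusted over the list alone (adjusted p = 0.0012 with an estimated correlation). Complement and coagulation genes had 20 of 25 higher, 20 adjusted over the list alone, with Plat, tissue-type plasminogen activator, at 9.61-fold and F3 at 19.4-fold (adjusted p = 0.0019 with an estimated correlation). Monocyte and macrophage genes had 18 of 21 higher and 1 lower, 18 and 1 adjusted over the list alone, with Ly6c2 at 21.4-fold and Arg1, arginase, at 7.499-fold (adjusted p = 0.01 with an estimated correlation). Interferon-stimulated genes had 21 of 25 higher, 22 adjusted over the list alone, with Gbp2 at 22.97-fold and Iigp1 at 17.8-fold, a lower bound (adjusted p = 0.0398 with an estimated correlation). Collagen and fibroblast genes had 19 of 23 higher and 1 lower, 20 and 1 adjusted over the list alone, with Dcn at 17.3-fold and Fn1 at 10.5-fold (adjusted p = 0.0321 with an estimated correlation). Regenerating epithelium genes had 20 of 25 higher, 21 adjusted over the list alone, with Ly6c1 at 12.3-fold (adjusted p = 0.0321 with an estimated correlation). Hypoxia and glycolysis genes had 18 of 25 higher, 18 higher and 1 lower adjusted over the list alone (adjusted p = 0.0321 with an estimated correlation). Epithelial antimicrobial genes had 13 of 23 higher and 5 lower, 13 and 5 adjusted over the list alone (adjusted p = 0.0398 with an estimated correlation).

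The other lists that moved in KO lost the call with an estimated correlation. Oxidative phosphorylation genes had 24 of 31 lower and none higher, 28 lower and 1 higher adjusted over the list alone (adjusted p = 0.1031 with an estimated correlation). Goblet cell genes had 17 of 25 lower and 2 higher, 18 and 2 adjusted over the list alone, and enteroendocrine genes 11 of 21 lower, 13 adjusted over the list alone (adjusted p = 0.0836 and 0.0935 with an estimated correlation). Colonocyte genes had 15 of 27 lower and 2 higher, 17 and 2 adjusted over the list alone, and PPAR targets 15 of 30 lower and 2 higher, 18 and 2 adjusted over the list alone (adjusted p = 0.1563 for both with an estimated correlation). Xenobiotic metabolism genes had 18 of 39 lower and 2 higher, 23 and 2 adjusted over the list alone (adjusted p = 0.1492 with an estimated correlation). Junction and keratin genes had 16 of 26 higher and 2 lower, 18 and 2 adjusted over the list alone, and immediate early genes 14 of 22 higher, 17 higher and 1 lower adjusted over the list alone (adjusted p = 0.08 and 0.1031 with an estimated correlation). T and NK cell genes had 12 of 20 higher, 15 adjusted over the list alone, and MHC class II genes 9 of 13, 9 adjusted over the list alone (adjusted p = 0.0711 and 0.0836 with an estimated correlation). Endothelial genes had 8 of 20 higher, 9 adjusted over the list alone (adjusted p = 0.1649 with an estimated correlation). Smooth muscle genes had 5 of 20 higher, squamous genes 5 of 19 and adipocyte genes 3 of 14 lower, against 5, 8 and 3 adjusted over the list alone (adjusted p = 0.3860 for each with an estimated correlation). Cell proliferation genes had 1 of 29 lower and a median of -0.44, with none passing adjusted over the list alone (adjusted p = 0.6316 with an estimated correlation). That list lost its call without KO lesion 1 (median -0.27, adjusted p = 0.0938), and its median was -0.28 without KO control 2 and -0.66 without KO lesion 3, and adipocytes lost theirs without KO control 3 or KO lesion 3 (adjusted p = 0.2768 and 0.1061).

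With the number series as a covariate 2514 genes passed in the KO response, 1389 higher and 1125 lower, of which 2352 were among the 6472. With the series as a random block 5433 genes passed, 2412 higher and 3021 lower, of which 5423 were among the 6472. The series itself passed in 1 gene, and the correlation within a series was 0.0519. KO controls and KO lesions come from different number series, so the series effect in this comparison is estimated from WT controls alone. Within the lower number series 3641 genes passed in the WT response, 2110 higher and 1531 lower, of which 2936 were among the 4714.

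The log2 changes of the 2 responses correlated across genes at r = 0.80 (Spearman rho = 0.55), and the responses share no array. Genes are not independent replicates, so no p is given. Of the genes, 1615 were higher in both and 1762 lower in both, against 192.7 and 310.7 for independent lists, and 4 were called in opposite directions. Of the 4714 genes called in WT, 4533 had the same sign in KO.

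**Figure D2:**
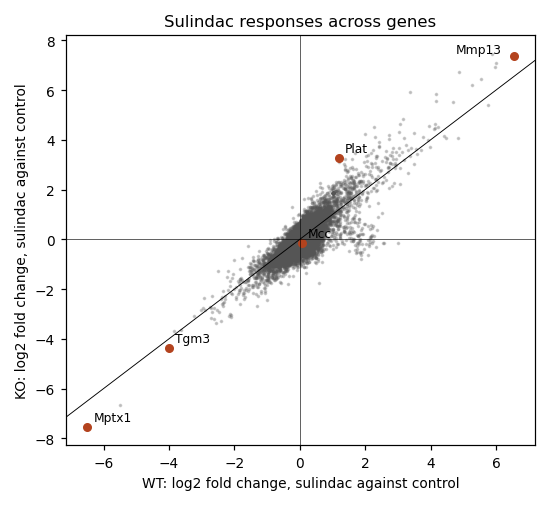
Log2 fold change of each of the 30705 genes on sulindac against control in WT (horizontal) and KO (vertical), with the line of equal change. Plat lies above the line in KO, and Mcc lies near 0 in both.

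**Figure D3:**
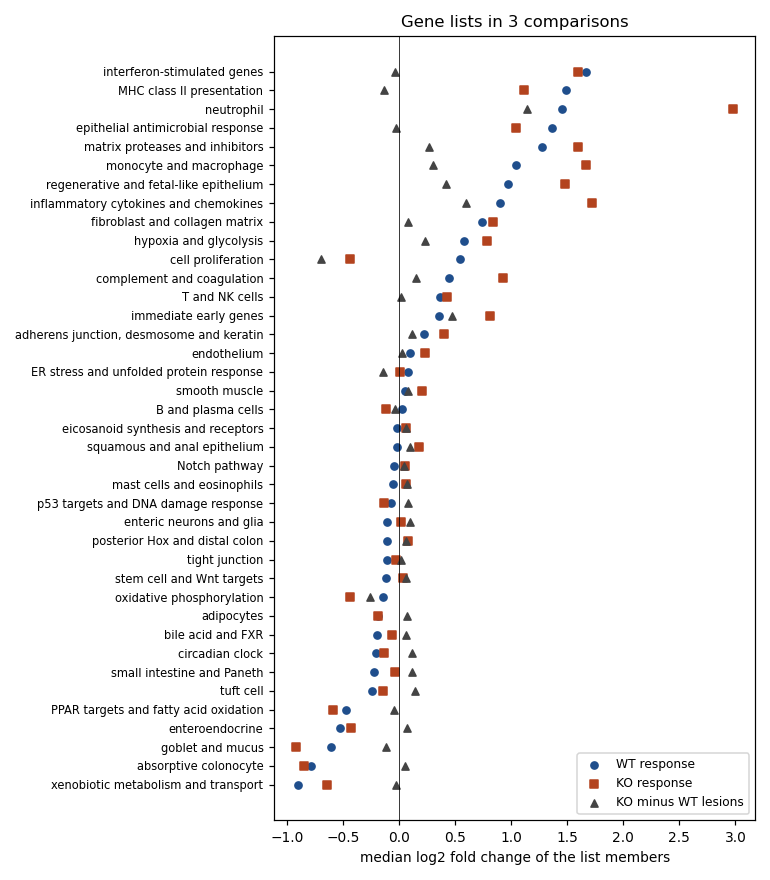
Median log2 fold change of the members of each of the 39 gene lists in the WT response (circles), the KO response (squares) and the difference between KO and WT lesions (triangles). Neutrophil genes have medians of 1.45, 2.98 and 1.14 in that order.

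On the control diet no gene differed between KO and WT by the limma test, with 641 genes at an unadjusted p under 0.05. Mcc had the lowest p. Mt1, a metallothionein, was 1.01 (SE 0.20) higher on the log2 scale in KO without passing, and Esp23, Gm12165 and A630001G21Rik differed by -0.31, -0.38 and 0.37, each with an adjusted p of 0.9995. Cell proliferation, B and plasma cell and MHC class II lists were higher, with medians of 0.29, 0.13 and 0.13. None of these members passed over all genes, 3 of the 19 B and plasma cell genes were higher adjusted over the list alone, and none of the 3 lists held (adjusted p = 0.9463, 0.7590 and 0.9463 with an estimated correlation), and fry called 0 lists. The proliferation median was 0.17 without KO control 2 and 0.46 without KO control 3, that of B and plasma cells 0.0458 and 0.23, and that of MHC class II 0.0431 without KO control 2 and 0.21 without WT control 4. Without KO control 3, 2 genes and 9 lists passed, and with the replicate block 8 lists did. Without KO control 2 the B and plasma cell list lost its call (adjusted p = 0.0744) and so did MHC class II (adjusted p = 0.5889), which also lost it without KO control 1 (0.0908) and without WT controls 2, 5 or 6 (0.0669, 0.0805 and 0.0822).

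Between KO and WT lesions on sulindac, Plat had the lowest p of the named genes. It was 4.004-fold higher in KO lesions (log2 2.001, SE 0.128, adjusted p = 2.6e-06), at 8.91 ± 0.31 (SD, n = 4) against 6.91 ± 0.08 (SD, n = 3). Of 20 neutrophil genes 4 passed, among them Retnlg, 4.88-fold higher in KO lesions, Cxcr2, a chemokine receptor, 3.20-fold, and Trem1, a receptor that amplifies myeloid activation, 3.26-fold, and the list call was lost with an estimated correlation (adjusted p = 0.2190). Mrgpra2a, Olr1, Il1f9 and Lilr4b were 4.58-fold, 4.36-fold, 3.60-fold and 3.20-fold higher. Immunoglobulin variable genes Igkv19-93, Ighv1-47 and Ighv3-4 were lower by log2 -2.90, -2.42 and -2.06, and Cdo1, Ccl8, Serpina3n and Cd177 by -1.42, -1.13, -0.91 and -0.84. Ighv3-4, Ighv1-47 and Ccl8 lay at 3.998, 4.30 and 4.54 in KO lesions, so their differences are lower bounds in size.

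In this comparison 94 genes passed, 76 higher and 18 lower in KO, 19 and 5 of them at least 2-fold. Fitting these groups alone left 1 gene, Plat, and the replicate block left 2, Plat and Gm9733, the latter named after its values were seen; every other gene named for this comparison lost its call there. Leaving out KO lesions 1, 2, 3 and 4 in turn gave 19, 24, 1697 and 52 genes, and without KO lesion 3 the balance turned, with 687 higher and 1010 lower in KO, and leaving out WT lesions 1, 2 and 3 gave 4, 7 and 7. Apart from Plat and Mcc, each named gene lost its call in 3 to 6 of these 7 fits. KO lesion 3 had an inflammatory list mean of 6.48, against 7.32 to 7.71 in the other KO lesions and 6.43 to 6.83 in WT lesions. In the main fit the p-values between lesions use 1 spread per gene pooled over all 16 arrays, controls included. The 8 largest rises taken by the rule for named genes had SDs of 0.31 to 1.25 in KO lesions. In KO controls their SDs were 0.06 to 0.19, so the pooled spread can understate that of the lesions.

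Oxidative phosphorylation, cell proliferation and neutrophil lists had the lowest p between the lesions by camera at the preset correlation. Of 20 neutrophil genes 4 were higher in KO, 14 adjusted over the list alone, with a list median of 1.14 (adjusted p = 0.2190 with an estimated correlation). Oxidative phosphorylation genes between lesions had 2 of 31 lower, 11 adjusted over the list alone, with a median of -0.26 (adjusted p = 0.2190 with an estimated correlation). Uqcrfs1 and Ndufs3, subunits of complexes III and I, were lower by log2 -0.43 and -0.40. Cell proliferation genes had a median of -0.69 with no member passing over all genes or adjusted over the list alone (adjusted p = 0.3608 with an estimated correlation). With the inflammation covariate that median was -0.16, and the list mean differed by -0.15 with a 95% interval from -1.01 to 0.71. F3, Adam8, Pfkfb3 and Jun were higher by 0.97, 0.85, 0.78 and 0.54. Immediate early genes had 1 of 22 higher, 14 adjusted over the list alone, and regenerating epithelium genes 1 of 25, 8 adjusted over the list alone (adjusted p = 0.3265 for both with an estimated correlation). Matrix proteases had 2 of 21 higher, 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.2190 with an estimated correlation). Cytokines and chemokines had 1 of 32 lower, 13 higher and 1 lower adjusted over the list alone (adjusted p = 0.3608 with an estimated correlation). Complement genes had 2 of 25 higher, 9 adjusted over the list alone, and lost the call with the replicate block (adjusted p = 0.0520, and 0.3608 with an estimated correlation) and without WT lesion 1 or KO lesion 2 (adjusted p = 0.0706 and 0.0811). Some lists share called members, so their calls are not independent. Plat is in the matrix protease and complement lists, and F3 in the regenerating epithelium and complement lists. Of 17 lists moved, none held with an estimated correlation, and fry called 6.

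The response to sulindac differed between genotypes in 1 gene, Plat. Its interaction was 2.06 (SE 0.17, adjusted p = 1.35e-04), as it rose by 3.26 in KO and by 1.20 in WT on the log2 scale, and its genotype difference on the control diet was -0.0625. Gm9733, Tmem95, Gm11714 and Siglece had interactions of 1.20, 0.67, 1.04 and 0.84 without passing, with limma adjusted p of 0.1172 for Gm9733 and 0.2566 for the rest. In WT and KO controls Gm9733 lay at 3.84 and 3.69, Gm11714 at 3.86 and 3.65 and Siglece at 4.66 and 4.56. These values are under the array medians, so the interactions of these genes are uncertain in size. Cell proliferation genes had a median interaction of -0.95, from medians of 0.55 in WT and -0.44 in KO. No member passed over all genes and 23 of 29 were lower adjusted over the list alone (adjusted p = 0.4955 with an estimated correlation). Neutrophil genes had a median interaction of 1.14, with 15 of 20 higher adjusted over the list alone (adjusted p = 0.4955 with an estimated correlation). Of 17 lists moved in the interaction, none held with an estimated correlation, and fry called 1. Leaving out KO lesion 3 gave 518 genes, 280 higher and 238 lower, leaving out KO lesion 1 gave 5, and leaving out KO lesion 2 or WT lesion 2 gave 2.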

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

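Tests chosen only after their results were seen are those of a difference tied to genotype and of a single array for Plat, of the epithelial share, and both tests of KO lesion 3; the inflammation covariate itself was also added after the data were seen.

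Of 162 groups of values examined for an array far from the others, 11 held such an array, where chance gives about 8.1. In WT controls, array 4 was high for Cxcl9 (6.31) and Iigp1 (5.31), and array 3 was low for Mptx1 (7.91) and Mptx2 (6.61) and high for the list of PPAR targets and fatty acid oxidation (8.66). WT control 2 was low for Trpm6 (8.95), and WT control 5 was high for Scin (10.87). In KO lesions, array 2 was high for Mmp10 (11.81) and Cyp2c68 (6.78), array 1 was low for Ccl8 (4.03), and array 3 was low for interferon-stimulated genes (7.46 against 8.29 to 8.39).

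Responses differed between genotypes by the interaction test for Plat (2.06) and for 17 gene lists, none of which held with an estimated correlation. Of these lists, fry called 1, the matrix proteases, which hold Plat, so that call is not separate from the Plat result. The median interactions were 1.14 for neutrophil, 0.53 for inflammatory cytokine, 0.43 for immediate early, 0.39 for regenerative epithelium, 0.34 for matrix protease and 0.24 for macrophage genes. They were 0.16 for hypoxia, 0.15 for complement, 0.15 for collagen, 0.15 for neuron and glia, 0.14 for squamous and 0.13 for junction and keratin genes. They were -0.95 for proliferation, -0.30 for oxidative phosphorylation, -0.24 for B and plasma cell, -0.20 for ER stress and -0.16 for goblet genes. Single arrays moved several of these medians. Goblet was -0.0704 and -0.25 without WT lesions 1 and 3, and -0.31 and -0.0530 without KO lesions 2 and 4. B and plasma cell was -0.0847 and -0.37 without KO controls 2 and 3, and ER stress -0.13 without KO control 2. Collagen was 0.27 without KO control 3 and 0.23 without KO lesion 4, and regenerative epithelium 0.25 without WT lesion 3. Hypoxia was 0.26 without WT control 2, 0.28 and 0.24 without WT lesions 2 and 3, 0.30 and 0.27 without KO controls 1 and 2, and 0.25 and 0.27 without KO lesions 2 and 3. Calls ended for macrophage genes without WT lesion 1 (adjusted p = 0.0861), for hypoxia without KO control 3 (0.1290) and for complement without WT lesion 1 (0.0519). They ended for collagen without WT lesion 1, KO controls 1 and 2 and KO lesion 3 (0.0860, 0.0570, 0.1432 and 0.1979). For junction and keratin genes they ended without WT control 5, WT lesion 1, KO control 3 and KO lesions 1 and 3 (0.0685, 0.1604, 0.3402, 0.1061 and 0.0871), with a median of 0.0848 without KO control 3. Transcript clusters with no named gene, which no comparison used, changed in 1403 cases in the WT response and 2379 in the KO response.

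Plat stood 2.001 higher in KO than in WT lesions on the log2 scale. With the inflammatory list mean as a covariate over the 7 sulindac arrays the difference was 1.84, with a 95% interval from 1.40 to 2.28. The call ended there (adjusted p = 0.2741). The SE was 0.128 with all arrays, 0.160 with the lesions alone, where the adjusted p was 0.0435, and 0.190 with the covariate. Putting back the difference, the SE or the degrees of freedom of the fit of the lesions alone, 1 at a time, left p times the number of genes at 0.2525, 0.1381 and 0.3019, so none of them restored the call by itself. Each fit leaving out 1 sulindac array gave at least 1.90 with a limma adjusted p of at most 7.21e-05. Plat was named by a rule that asks for lesions that do not overlap. These fits are therefore no separate evidence against a single array. The control diet difference was -0.0625, which argues against a variant that acts in every KO array at any level of the gene. Plat was only at 5.71 in WT and 5.65 in KO controls, so a variant that shows once the gene is raised stays open. A response of Plat to epithelial Mcc loss in damaged tissue may remain as a hypothesis, which Plat levels in KO and WT lesions matched for severity and litter would test, and litter or housing stays untested.

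Oxidative phosphorylation genes had a median of -0.26 in KO against WT lesions. The median nearest to 0 with 1 array left out was -0.22, and with the inflammation covariate it was -0.21, with an upper 95% bound of -0.04 for the list mean. Colonocyte genes had a median of 0.0571 and junction and keratin genes 0.11, each above that median by more than the SE of its list mean (0.26 and 0.05). The 95% intervals of the list means were -0.02 to 0.25 for junction and keratin genes and -0.02 to 0.11 for tight junction genes. With the inflammation covariate they were -0.05 to 0.34 and -0.06 to 0.14. The junction and keratin mean rose from controls to lesions, from 9.45 to 9.66 in WT and from 9.42 to 9.78 in KO, so it can hide a lower share of epithelium. The tight junction mean did not rise (7.81 to 7.71 in WT, 7.77 to 7.76 in KO). Its intervals argue against a lower share of the whole epithelium only so far as that list follows this share, which was not tested. Leaving out 1 array gave junction and keratin medians from 0.0545 (without KO lesion 1) to 0.14. Goblet genes had a median of -0.12 (-0.0758 and -0.22 without WT lesions 1 and 3, -0.23 and -0.0312 without KO lesions 2 and 4), and with the covariate colonocyte and goblet genes had medians of -0.21 and -0.33, as low as oxidative phosphorylation genes or lower. The colonocyte list mean had an interval from -0.63 to 0.70. A lower share of the epithelium and a loss of differentiated epithelial cells therefore both stay open. Whether junction genes rose in the remaining epithelium was not tested. Since the list call is lost with an estimated correlation, the pattern may be chance.

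The count of genes between KO and WT lesions was 94 with all arrays and 1697 without KO lesion 3. Its Mcc (6.48) lay with the other KO lesions and outside the WT range, which argues against a WT lesion under its label. Its Plat (8.66) lay there too, but Plat was named by a rule that asks for lesions that do not overlap. Plat is therefore no further evidence on the label. Its inflammatory list mean was 6.48, within the WT lesions (6.43 to 6.83) and below the other KO lesions (7.32 to 7.71). A milder lesion is a candidate explanation. How severe each lesion was is not given in the labels.

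Other splits of the samples were refitted to see how often chance gives counts as large. In the WT response 1 of 84 splits, the real one, gave 4714 genes (highest other 93), which argues against chance as the source of that count. In the KO response 1 of 35, again the real one, gave 6472 (highest other 4863). No share under 1 of 35 is possible there, so the splits argue against chance only weakly. The KO split is also that of the number series, and with the series as a covariate 2514 genes passed. Among the 8 splits that part all 3 pairs of replicate numbers, the highest other count was 5 in the WT response and 21 in the genotype difference on sulindac, against 94. For that difference, 3 of 35 splits gave 94 or more, the highest 2369 from setting KO lesions 1, 2 and 4 against the rest, which points to a structure of the samples. Chance is not excluded for it, nor for the interaction, where 13 of 100 drawn splits reach 1 (highest other 731). On the control diet the real count is 0, which all 84 splits reach by construction, so the splits say nothing about chance there (highest other 769, from WT controls 1 and 2 with KO control 3). The high counts of other splits also point to a structure of the samples. For gene lists, 14 of 84 splits reached 25 in WT (highest other 27), 4 of 35 reached 25 in KO (highest other 28), 75 of 84 reached 3 on the control diet (highest other 17), 16 of 35 reached 17 on sulindac (highest other 27) and 19 of 100 reached 17 in the interaction (highest other 25). Chance is not excluded for any count of lists, but the other splits do not measure chance alone. In WT, 1 split with 27 lists set WT controls 1, 3 and 6 against the rest, all 3 lesions among them. Such a split still carries part of the difference between lesions and controls, so these shares do not decide on the list counts.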

How the results depend on the processing

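The fits without WT controls 1 and 2, with the inflammation covariate and of all rows were chosen after seeing the data. No alternative reversed a named gene. The smooth muscle covariate turned the smooth muscle list, its own source, to -0.0702 in WT and -0.0223 in KO, and the series covariate turned the test's direction for proliferation in KO, with a median of -0.0466; the cause of the latter was not tested. The WT response kept a count within 1.5 times under each alternative (3157 to 4461 with 1 array left out). The KO response gave 4474 to 7006 with 1 array left out and 2514 with the series covariate; the cause was not tested. Between lesions the count was 1 with the groups compared alone, 2 with the replicate block, 58 with the series covariate, 29 with centred arrays, 714 with array weights, 20 with the smooth muscle covariate, 0 with the inflammation covariate (limma over 7 arrays, 1029 at an unadjusted p under 0.05, against 3188 for the groups compared alone, which are the same 7 arrays), 7 without WT controls 1 and 2, 5 of 72688 rows with all rows fitted, and 4 to 1697 with 1 array left out; the cause was not tested. On the control diet it was 1 with repeated quantile normalisation and with array weights, and 0 to 2 with 1 array left out. The interaction gave 1 to 518.

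Lists moved with an estimated correlation numbered 11, 10, 0, 0 and 0 in the order WT response, KO response, control diet, sulindac diet and interaction. With fry they were 27, 27, 0, 6 and 1 in that order. On the control diet the lists were 8 with the replicate block, 6 with array weights, 5 with the smooth muscle covariate and 5 without WT controls 1 and 2. With 1 array left out the lists ranged from 24 to 27 in WT, 24 to 27 in KO, 2 to 9 on control, 14 to 22 on sulindac and 13 to 23 in the interaction. Mcc on control was -0.60 under quantile normalisation and -0.59 under array weights, both past the threshold, and -0.66 to -0.53 with 1 array left out. On sulindac it was -0.79 with the groups alone, -0.82 with the replicate block and -0.79 with the inflammation covariate, none past it, and -0.86 to -0.70 with 1 array left out. The correlation of the responses was 0.71 with the replicate block, 0.84 with the series covariate, 0.85 without WT controls 1 and 2, and 0.75 to 0.84 with 1 array left out. The replicate block ended the calls between lesions of all named genes except Plat, and also those of B and plasma cell and smooth muscle lists in WT, adipocytes in KO, complement between lesions, and macrophage, goblet and hypoxia lists in the interaction, and changed no other named call. Over all alternatives but left-out arrays, and apart from Mcc between genotypes, named genes with a call kept it in 791 cases and lost it in 141, all of the latter between lesions, and named genes without a call gained none in 128 cases. Signal over background is not known from RMA values.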

Other observations

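The gene families by symbol, the neutrophil comparison with other immune cells and the test of a response taken further were chosen after the results were seen.

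Immunoglobulin variable genes moved as families in the WT response and between lesions at the preset correlation alone. Of 117 Ighv genes 65 were higher in WT lesions than in WT controls, with a family median of 1.32 (adjusted p = 0.3949 with an estimated correlation), and of 86 Igkv genes 24 were higher, with a median of 1.07 (adjusted p = 0.4016 with an estimated correlation). In KO against WT lesions 2 of 117 Ighv and 1 of 86 Igkv genes were lower, with medians of -0.99 and -0.85 (adjusted p = 0.5220 for both with an estimated correlation). Mitochondrial ribosomal protein genes had medians of -0.33 (Mrpl, 50 genes) and -0.26 (Mrps, 30 genes) in KO against WT lesions, with no member passing (adjusted p = 0.5220 for both with an estimated correlation). In the KO response 26 of 50 Mrpl genes and 14 of 30 Mrps genes fell (adjusted p = 0.6513 and 0.6293 with an estimated correlation). These medians kept their sign under repeated quantile normalisation and with centred arrays. Of 144 families tested, none called at the preset correlation held with an estimated one.

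Neutrophil genes were higher in KO than in WT lesions by a median of 1.14, and at least 1.004 with any 1 sulindac array left out, but 4 of 20 members passed and the list call was lost with an estimated correlation (adjusted p = 0.2190), so the excess may be chance. T and NK cell genes had a median of 0.0185 and B and plasma cell genes -0.0389. Their list means were 5.57 and 5.88 in WT lesions and 5.57 and 5.76 in KO lesions. These lie not far above the array medians of 4.90 to 5.05, near which differences are compressed. The values of these lists therefore argue only weakly against an excess of all immune cells. Monocyte and macrophage genes had a median of 0.30 (0.23 to 0.35 with 1 array left out), so an excess of myeloid cells in general stays open. With the inflammation covariate the neutrophil median was 0.44, so part of it may follow the degree of inflammation. The list holds genes that other myeloid cells also express.

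Whether KO lesions went further along the response seen in WT was tested in 3 forms, and the form changed after results were seen. Both fold changes use the WT lesion arrays, which pushes their covariance below 0. It was -0.0025, above the simulated mean of -0.0138 for unchanged groups that share the arrays and above the highest of 100 simulations (-0.0130). The simulations leave out that lesions of the same replicate number deviated together (r from 0.35 to 0.63), which moves the covariance of unchanged groups towards 0, so the distance may come from that in part. They also drew genes independently, with 1 SD per gene pooled over all groups. Their range is therefore narrower than correlated genes would give, and a value above it does not exclude chance. The correlation was r = -0.03, against a mean of -0.62 in those simulations and of -0.21 with the WT response kept. Medians of genes raised or lowered in WT are not used, since those genes were chosen with the same WT lesion arrays and no value for unchanged groups was computed. The hypothesis stays open.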
